A study of Mus musculus with 4 samples.

How the data were processed

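Total RNA from whole skin of newborn mice (postnatal day 0, strain FVB/N) was labelled with biotin and hybridised to Affymetrix expression arrays, per the labels' protocols. The 4 arrays fall into 2 groups, loricrin knockout and wildtype, with 2 arrays each. They lie on 2 array types that carry different probe sets, so each array type holds 1 array per genotype. The second array of each genotype is titled a replicate in the labels, but it is on the second array type and therefore repeats only those genes that both types measure. The labels do not say whether the replicate arrays held RNA of other animals or the same RNA.

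The values used are the authors' deposited array intensity values, 1 signal per probe set and array on a linear scale. They were made with MAS5, per the submitters' processing notes, a method that subtracts local background and combines the perfect-match and mismatch probes of a probe set into 1 signal. The MAS5 version, its scaling target, detection calls and filters are not given in the sources used here. All 4 deposited columns shared nearly the same 2% trimmed mean signal, between 500.2 and 500.4, which is the MAS5 form of scaling. The median signal was 135 and 141 on the knockout and wildtype arrays of the first type, and 203 and 210 on those of the second. No signal was 0 or below. Each column was matched to its sample by name, and no column was left unmatched.

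From these values the 2 arrays of a type were set to an equal 2% trimmed mean. A floor was placed at the mean of their 40th percentiles, 77.6 on the first type and 133 on the second, and lower signals were set to it. The log2 ratio of knockout over wildtype was then taken per probe set. A ratio with 1 signal at the floor is a lower bound on the fold and is written as "at least". The 66 control probe sets of each type were left out after scaling, which left 12422 and 12411 probe sets. Of these, 10833 and 10581 name 1 gene in the platform annotation, 396 and 178 name several and 1193 and 1652 are not listed with a gene. Genes were named only from probe sets with 1 gene, except for the Sprr2a probe sets below, which are said to name several. Symbols were updated through the gene identifier with a RefSeq gene table of a mouse reference assembly, which held 10817 and 10550 of them, while 16 and 31 kept the annotation's symbol. No genome build applies to these arrays and no coordinates were used.

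With 1 array per genotype and type, no test was possible within a type. Probe sets were counted by a rule of size instead, at least 2-fold higher or lower in knockout, and the words higher and lower below refer to that rule. A gene with several probe sets on a type took the one with the highest mean signal. For 28 gene lists of skin cell types, structures and pathways, the median log2 ratio of the members whose mean log2 signal lay above the floor was set against 10000 random lists of the same size, matched on mean signal in 10 bins, where a list had at least 3 such members. The percentile describes these arrays and is no test. For genes on both types, the log2 ratios of the types were correlated, and limma (lmFit and eBayes, Benjamini-Hochberg adjustment) compared the genotypes over all 4 arrays with the array type as a block. Nothing says that the arrays came from separate animals, so its p-values measure no spread between animals. Each gene had 1 residual degree of freedom against 15.4 from the prior. The p-values thus rest mostly on the disagreement between the array types pooled over all genes.

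The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. That rule took loricrin first, then per array type the 12 genes furthest in each direction with both signals above the floor, the 5 largest bounds in each direction, 2 to 4 list members past 2-fold (or, for a list with none, its 2 members of highest mean signal), and genes past 2-fold the same way on both types or past limma's adjusted p of 0.05. Genes named outside it are said to be chosen after their values were seen. The fixed alternatives covered scaling (values as deposited, median log2 ratio of 0, quantile, loess), the floor (20th or 60th percentile, none with a pseudocount of 1, or the floor's value added as a pseudocount), the rule of size, probe set suffixes, the value per gene and the block. A scaling on 9 bacterial spike-in probe sets and a cornified envelope list without loricrin were added after the data were seen.

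The steps were first tested on simulated data. For the knockout against wildtype comparison on the first array type, with 200 of 12422 probe sets changed, the rule of size recovered 54.5% of those changed by 2-fold and 100% of those changed by 4-fold, with 25 and 29 false calls. On the second type, with 200 of 12411 changed, it recovered 47.5% and 99.0%, with 72 and 77 false calls. For genes on both types, limma recovered 200 of 200 genes changed by 4-fold among 1082, with 2 false calls, where each change was planted alike on both types. For the rule of size, changes were planted only in probe sets well above the floor. The simulated noise had the same size at every signal level. Changes of 2-fold lay at the cutoff itself, so the noise decided their recovery. These figures therefore do not give the error rate of the real calls, many of which lie near the floor. The number of arrays limits the precision of every value. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1.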

Results

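Gene expression was measured in whole skin of newborn mice that lacked loricrin, the main protein of the cornified envelope of terminally differentiated epidermis, and of wildtype mice of the same strain. The comparison asks which skin transcripts differ at birth when loricrin is missing. There were 2 arrays per genotype, 1 on each of 2 array types. The first type measured 8251 named genes and the second 7542. Of the tested probe sets, 7904 on the first type and 8142 on the second had a signal above the floor in at least 1 of the 2 arrays. Because each type held 1 array per genotype, the ratios below have no replicate error unless both types are named.

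Loricrin itself was checked first. Its brighter probe set read 2013 in the knockout and 41224 in the wildtype on the first array type, a log2 ratio of -4.36 or 20.5-fold lower in knockout. The ratio was -3.67 under the spike-in scaling described below. A second loricrin probe set on that type lay below the floor in both arrays, and the second type has no probe set listed for loricrin, so loricrin checks the genotype labels of the first type only. The position of these probes relative to the deleted sequence was not given.

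The arrays also differed in sex-linked transcripts, which were looked at after the data were seen. Xist, the RNA that silences an X chromosome in female cells, read 857 in knockout and 24.7 in wildtype on the first type. The Y-linked Eif2s3y read 42.7 and 1071. On the second type the Y-linked Kdm5d read 27.8 in knockout and 470 in wildtype on one probe set and 12.2 and 976 on another, and Xist read 129 and 12.5, both below the floor there. On both types the knockout array thus carried the female pattern and the wildtype array the male one, so sex and genotype could not be separated in any comparison here.

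On the first array type the list with the most genes past 2-fold was that of the extracellular matrix of the dermis, and these genes were lower in knockout skin. Of 22 measured dermal fibroblast and matrix genes, 11 were at least 2-fold lower, none was at least 2-fold higher, and the list median was -1.25, below all 10000 matched random lists. The fibrillar collagen chain Col1a1 read 172 against 1545, a log2 ratio of -3.17, and Col3a1 was at least 12.6-fold lower. Elastin (Eln) was at least 8.71-fold lower, the small proteoglycan biglycan (Bgn) 5.72-fold, Col6a3 5.02-fold, Col6a2 3.88-fold and the microfibril protein Mfap2 3.85-fold. The dermal transcription factor Twist2 was 4.96-fold lower, with a knockout signal of 79.5 just above the floor. The other 11 did not pass 2-fold. Among them decorin (Dcn), chosen after its value was seen, read 2462 and 2556. The 2 probe sets of Col1a2, also chosen after its values were seen, differed, with log2 ratios of -3.66 on one and 0.01 on the brighter one that the rule takes. The list median stayed between -1.40 and -0.55 under the alternatives fixed beforehand, the last with the floor added as a pseudocount, and was -0.56 under spike-in scaling. The knockout array in which these genes were lower also carried the female pattern of sex-linked transcripts.

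Several red cell transcripts were lower in the same array. Adult haemoglobin genes Hba-a1 and Hbb-b2 were 4.01-fold and 3.78-fold lower, with Hba-a1 at 3792 against 15206, and Alas2, the first enzyme of erythroid haem synthesis, was at least 3.23-fold lower. The embryonic globin gene Hbb-bh1 went the other way, 2.58-fold higher, but at low signal. It read 202 in knockout and 78.3 in wildtype, the latter just above the floor. The 11 measured erythroid genes held 3 lower and 1 higher, and their median of -0.33 lay at the 2.70th percentile of matched random lists (0.36 at the 3.55th under spike-in scaling). It lay outside the central 95% of random lists under 7 of the 9 alternatives fixed beforehand, and moved most with the floor, to -1.04 (below all random lists) with it at the 60th percentile.

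Several small proline-rich proteins of the SPRR2 family, cornified envelope precursors that transglutaminases cross-link, were higher in knockout skin. Of 12 measured SPRR genes 4 were at least 2-fold higher and none lower, and the list median was 0.86, above all 10000 random lists. Sprr2c-ps, by its symbol a pseudogene, read 2419 against 666, 3.63-fold higher. Sprr2i was 2.67-fold, Sprr2h 2.38-fold and Sprr2e 2.26-fold higher. The other 5 SPRR2 genes, a further pseudogene among them, had log2 ratios from 0.12 to 0.96. Sprr1a, Sprr1b and Sprr3, chosen after their values were seen, had log2 ratios of -0.16, -0.35 and -0.68. Outside the list, probe sets that name several Sprr2a genes were higher too, and were looked at after their values were seen. They read 12962 against 5288 (2.45-fold) and 11059 against 3985 (2.77-fold). Most SPRR2 probe sets are marked as shared by a sequence family, so the signal of a single member is uncertain. Second-type probe sets for SPRR genes are not listed.

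Other genes of the epidermal barrier shifted little. Without loricrin, none of 12 measured cornified envelope genes passed 2-fold, and the list median was -0.45, at the 0.08th percentile. Krtdap and Crct1, its brightest members, had log2 ratios of -0.58 and -0.51. None of 10 cross-linking enzymes, proteases and inhibitors passed 2-fold, with a median of -0.43 at the 0.10th percentile, and the protease Asprv1 had a ratio of -0.60. None of the 9 measured genes of the keratin list passed 2-fold. Krt1 stood at -0.51 and Krt10 at -0.47. The others, named after their values were seen, were Krt2, Krt4, Krt7, Krt8, Krt13, Krt19 and Krt77. The list median of -0.39 is the value of Krt4, while Krt2, Krt7 and Krt77 were positive, at 0.25, 0.27 and 0.21. Under quantile normalization the median was 0.034. None of 16 cytosolic ribosomal protein genes passed 2-fold, with a median of -0.49 below all random lists and Rpl41 at -0.63. Several of these genes, such as Krtdap, Krt1 and Krt10, are among the brightest on the array, but Krt4, at 617 and 807, is not. Scalings that depend on signal brought most of the medians closer to 0. Under quantile normalization the cornified envelope median with loricrin was -0.030 (28.3rd percentile) and the ribosomal median -0.034 (24.1st), and under loess they were -0.16 (2.55th) and -0.13 (4.06th), all inside the central 95% of random lists. The keratin median under loess was -0.13 (14.4th), while the protease list stayed outside under both, at -0.22 and -0.25. All 4 medians turned positive under the spike-in scaling, between 0.18 and 0.30, where they still lay at or below the 0.745th percentile.

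Among genes that join the epidermis to its basement membrane, several were higher in knockout. In the adhesion and tight junction list of 22 measured genes, 3 were higher and none lower. They were integrin alpha 6 (Itga6), 3.06-fold, the hemidesmosome collagen Col17a1, 2.68-fold, and the laminin chain Lamb3, 2.29-fold. The list median was -0.048, at the 36.8th percentile. A narrower list of hemidesmosome and basement membrane genes, drawn up after the data were seen and partly because of these genes, held 11 measured genes, 5 higher and none lower, with a median of 0.77 that lay between 0.74 and 1.46 over the scalings. Trp63, the transcription factor of basal keratinocytes, was 2.09-fold higher and the receptor gene Fgfr2 2.65-fold. The basal keratins Krt5 and Krt14, chosen after their values were seen, read below the floor in both arrays and could not be compared. On the second type the basal keratin Krt15, chosen likewise, read 26582 in knockout and 22304 in wildtype, a log2 ratio of 0.25. Its probe set there carries a suffix for shared sequence.

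**Figure D1:**
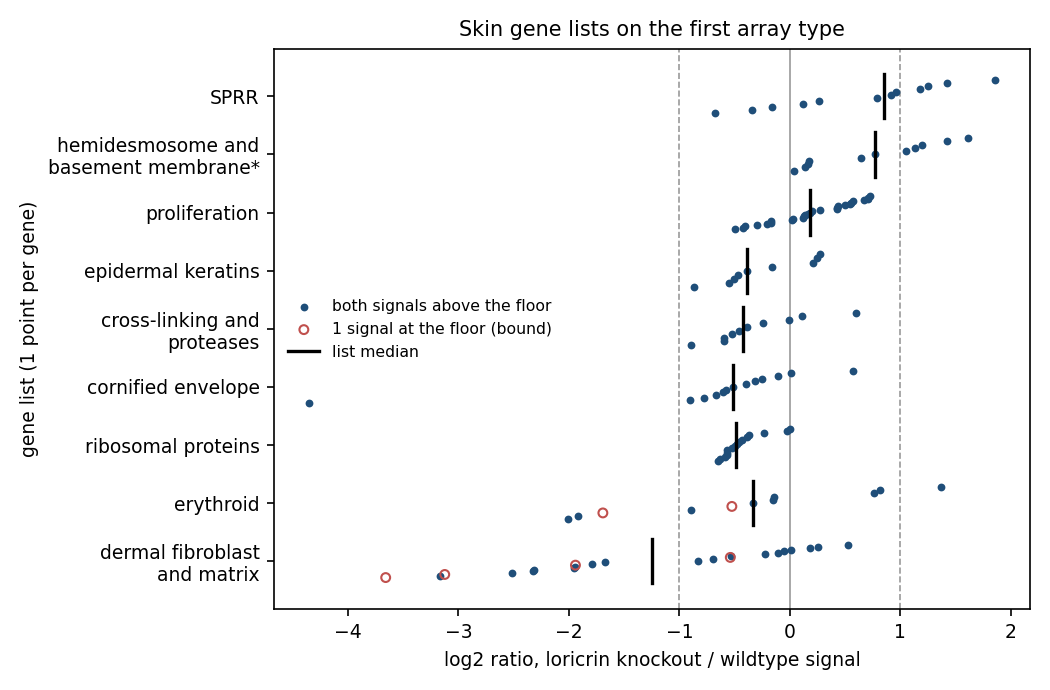
Log2 ratios of knockout over wildtype signal on the first array type (x axis) for the measured members of 9 gene lists (y axis), 1 point per gene from 1 array per genotype. Black bars mark list medians, open points have 1 signal at the floor, dashed lines mark 2-fold, and the starred list was chosen after the data were seen. The dermal median lies at -1.25 and the SPRR median at 0.86, and the leftmost cornified envelope point is loricrin at -4.36.

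In total 108 probe sets were at least 2-fold higher and 151 at least 2-fold lower in knockout on the first type, of which 33 and 64 are bounds. The transcription factor Zbtb16 was highest among genes measured in both arrays, at 4.47-fold, followed after Sprr2c-ps by Rab3a at 3.56-fold. The wildtype signal of Rab3a, 79.6, lay just above the floor. The chemokine Cxcl14 was 3.03-fold higher, the only member past 2-fold among 6 chemokines and cytokines whose median was -0.36 (2.44th percentile). That median was 0.054 with the floor at the 60th percentile and 0.33 under spike-in scaling. The stearoyl-CoA desaturase gene Scd1 was 2.47-fold higher. Beyond the matrix genes, the Wnt modulator Sfrp2 was 4.16-fold lower, the growth inhibitor Cdkn1c 3.76-fold, the growth factor midkine (Mdk) at least 11.7-fold and the transcription factor Sox11 at least 6.32-fold.

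Stress, inflammatory and proliferation programmes showed few changes of that size on the first type. Of 22 wound and stress genes only Krt16 passed, 2.24-fold lower. Of 28 antioxidant targets of Nrf2 only Gstm2 passed, 2.09-fold higher, and the list median was 0.16 at the 96.3rd percentile. None of 20 immediate early genes passed, although their median of 0.21 lay at the 98.9th percentile (96.5th under quantile normalization), with Fos at -0.17 and Jund at -0.63. None of 27 proliferation genes passed (median 0.18, Stmn1 0.57), none of 8 interferon genes (median -0.15, B2m -0.32) and none of 19 heat shock and unfolded protein genes (median 0.055, Hspd1 -0.12). Of 16 macrophage genes none passed, with a median of -0.11, Ctss at -0.31 and Csf1r at 0.20. Krt35 was lower and Krt86 higher among 19 hair genes, but another Krt35 probe set of similar signal had a log2 ratio of -0.03.

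The second array type gave 184 probe sets at least 2-fold higher and 228 at least 2-fold lower, of which 81 and 99 are bounds. Late cornified envelope genes, which form the outer envelope in late differentiation, were measured only here. None of 7 passed 2-fold, their median was -0.28 at the 3.54th percentile, and Lce1f, among the brightest, read 78409 in knockout and 95194 in wildtype. That median was 0.048 under quantile normalization and 0.37 under spike-in scaling. Most late cornified envelope probe sets carry suffixes for shared sequence, so the signal of a single member is uncertain here too. None of 7 other cornified envelope genes passed, with a median of 0.029, Sbsn at -0.17 and Cnfn at -0.08. None of 8 cross-linking enzymes and proteases passed, with Klk7 at -0.42 and a median of -0.24. None of 8 lipid barrier genes passed either, but their median of 0.36 lay at the 98.8th percentile, with the fatty acid elongase Elovl1 at -0.40. With the median over each gene's probe sets it was 0.13 (82.9th percentile).

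Hair follicle genes had the highest second-type list median, 0.58 at the 99.8th percentile, and of 6 measured 1 was higher, the hair shaft gene Krtap16-1, at least 3.72-fold. On the first type the 19 measured hair genes had a median of -0.10 at the 10.4th percentile. Only 3 immediate early genes were measured on the second type, with a median of 0.55 at the 99.7th percentile, Fosl2 at 0.55 and Klf6 at 0.62. The melanin enzyme gene Dct was 2.21-fold higher. Lactoperoxidase (Lpo) was at least 15.1-fold higher and Stat2, a mediator of interferon signalling, at least 8.85-fold, while the interferon-induced Bst2 was at least 2.89-fold lower. Among 8 antioxidant targets Slc7a11, a cystine transporter, was 2.59-fold lower, and the list median was -0.12. The knockout signal of Slc7a11, 135, lay just above the floor of 133. Kcnk3 was 3.83-fold and Megf6 3.58-fold higher. Igf1 was lower too, with a log2 ratio of -3.46 and a knockout signal of 138 just above the floor. Also lower were the chemokine Cxcl17, 4.08-fold, the elastic fibre protein Fbln5, 3.24-fold, and the microfibril protein Fbn2, at least 6.75-fold. The matrix gene Col14a1, the 1 dermal list member whose mean signal lay above the floor here, was at least 2.41-fold lower.

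The split between higher and lower depends on the scaling. The 9 bacterial spike-in probe sets, which hybridisation mixes carry in fixed amounts, had mean log2 ratios of -0.69 on the first type and -0.65 on the second. Scaling on them moved the median log2 ratio to 0.69 and 0.63 and gave 1432 higher against 51 lower on the first type, 96.6% higher in place of 41.7%. On the second it gave 1415 against 60, 95.9% higher in place of 44.7%. All directions above are therefore relative to the typical probe set. The floor moved the counts as well: with it at the 20th percentile they were 434 higher and 700 lower on the first type and 732 and 819 on the second, and at the 60th percentile 40 and 40, and 38 and 58. The largest changes and the list members past 2-fold, counted per array type and without loricrin, gave 93 entries. They include members of the lists chosen after the data were seen. Of these 93, 82 still passed 2-fold under spike-in scaling and 49 with the floor at the 60th percentile. Spike-in scaling raises the log2 ratios, so entries higher in knockout had to pass under it and only lower ones could fail. Among the 40 list medians with a value, 11 lay outside the central 95% of their random lists, 5 above and 6 below.

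Genes on both array types allowed the comparison to be repeated through other probe sets. Sox11, a transcription factor of embryonic tissue, was lower in knockout on both, with a log2 ratio of -2.66 or lower on the first type, where the knockout signal lay at the floor, and -1.17 on the second. With the floor value Sox11 was the 1 gene of 1082 to pass limma's test. Its mean log2 ratio was -1.92 (SE 0.30, limma adjusted p = 0.00874, lower on 2 of 2 types). That mean is a bound, and its SE and p rest on the floor and on variance pooled over genes. The ribosome biogenesis gene Esf1 was also lower on both, at -1.01 and -1.32, with an adjusted p of 0.0857 from limma. No gene was at least 2-fold higher on both. If the types were independent, 0.255 genes would be lower on both and 0.0924 higher. At an unadjusted p under 0.05 limma found 113 genes, where 54.1 are expected by chance. That excess was absent with the floor at the 20th percentile (84 against 81.7) and with no floor (85 against 106). No gene passed under quantile normalization or with the floor at the 20th percentile, and 8 passed under loess. Without the block no gene passed or had an unadjusted limma p under 0.05. Level differences between the types' probe sets then enter the residual, so that setting cannot check the excess or Sox11.

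The log2 ratios of the 2 types correlated weakly across these 1082 genes, which are not independent replicates (Pearson 0.178, Spearman 0.185), and 609 genes or 56.3% had the same sign. Of the 58 genes past 2-fold on at least 1 type, 36 had the same sign on the other. Krt16 read -1.17 on the first type and 0.51 on the second, and Igf1 -0.066 and -3.46, so a single ratio of this size need not hold on a second probe set. Dct had ratios of 0.74 and 1.14, and Bpgm -0.33 and -1.07.

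**Figure D2:**
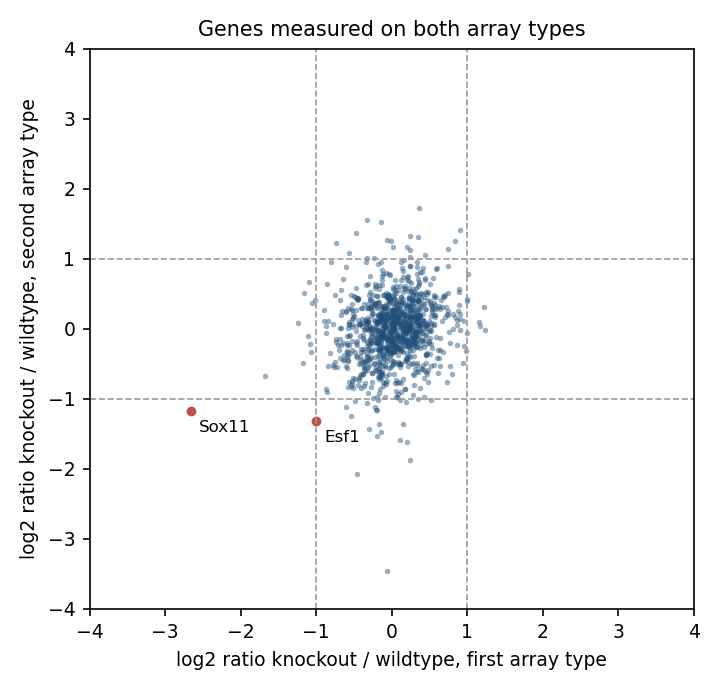
Log2 ratios of knockout over wildtype for the 1082 genes on both array types, first type on the x axis and second type on the y axis, 1 point per gene. Dashed lines mark 2-fold, and Sox11 and Esf1 are the 2 genes past it in the same direction on both (for Sox11 the first-type ratio is a bound). The cloud is nearly round, with a Pearson correlation of 0.178.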

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

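The spike-in scaling and the cornified envelope list without loricrin were chosen after the data were seen, and the other settings were planned. The counts moved with the floor and with spike-in scaling. In the order higher and lower on the first type, then higher and lower on the second, the 20th percentile as floor gave 434, 700, 732 and 819 probe sets, the 60th gave 40, 40, 38 and 58, and no floor gave 833, 1263, 1246 and 1361. A 3-fold rule gave 16, 48, 31 and 51, and 3 robust SDs among probe sets of like signal gave 57, 83, 43 and 71. The floor's value added as a pseudocount gave 59 and 110 higher. Spike-in scaling gave 1432, 51, 1415 and 60 probe sets and a loricrin log2 ratio of -3.67. Other scalings kept each count within 1.5 times. Loricrin stayed lower in every setting. List medians outside the central 95% numbered 11, and 17 with the floor at the 20th percentile. Spike-in scaling turned the first-type medians of the cornified envelope (0.18), protease (0.26), keratin (0.30), chemokine (0.33) and ribosomal (0.20) lists positive, quantile normalization that of keratins (0.034), and the 60th percentile as floor that of chemokines (0.054). The correlation between types was 0.117 with the floor at the 20th percentile, 0.287 at the 60th and 0.103 with none. The limma count of 1 gene became 0 under quantile normalization, with the floor at the 20th percentile and with none. It was 2 with the floor added as a pseudocount, 6 at the 60th percentile and 7 with median log2 ratio at 0. Loess gave 8. Spike-in scaling, which raises the log2 ratios as a whole, gave 597. With no replicate block the count was 0. Level differences between the types' probe sets then enter the residual, so that setting cannot check the count. Of the 13 lists with a median on both types, 5 had opposite signs there. Restricted to genes measured on both types, 6 lists kept enough members, and 1 of them had opposite signs. Leaving out single arrays was not run for limma, since no residual degrees of freedom remained. The labels give the arrays no replicate numbers, so the block was the array type, which pairs 1 knockout with 1 wildtype array. Except where a setting fixes it, the cause was not tested. Signals near the floor limit what these arrays resolve, since 4518 and 4269 probe sets lay below it in both arrays.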

Other observations

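The tests on a larger share of epidermis and on a shared SPRR2 transcript were chosen only after the result was seen, as was the spike-in scaling used in the scaling tests.

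Among 10 measured melanocyte and Schwann cell genes on the first type the peripheral myelin gene Pmp22 was at least 2.51-fold lower. Of 15 muscle genes 1 passed, the slow troponin Tnnt1, 2.21-fold higher, and of 6 nerve and cartilage genes 1 passed, Col9a3, 2.02-fold lower. None of 7 mast cell, dendritic cell and lymphocyte genes passed (median 0.077, Cd74 0.16), none of 30 oxidative phosphorylation genes (median -0.17, Cox6c -0.50) and none of 12 common reference genes (median -0.19, Eef1a1 -0.56). Of 16 lipid barrier genes on the first type Scd1 passed (median 0.11), of 23 epidermal transcription regulators Trp63 (median 0.11), and of 7 adipocyte genes Scd1 (median 0.28). First-type medians not given before were -0.13 for 22 wound genes, -0.20 for the muscle, 0.14 for the melanocyte and Schwann cell and 0.097 for the nerve and cartilage list. On the second type, medians not given before were 0.15 for 5 keratins, -0.046 for 6 wound genes, 0.087 for 13 transcription regulators, -0.22 for 8 adhesion genes, 0.55 for 4 interferon genes, 0.38 for 3 melanocyte genes and -0.14 for 5 oxidative phosphorylation genes.

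Some probe sets of a gene disagreed far beyond the 2-fold rule. A probe set of Fbln1, chosen after its values were seen, read 15720 in wildtype and 82.5 in knockout on the first type, a log2 ratio of -7.57, while its other 3 probe sets had ratios of 0.15, -0.22 and 0.079. On the second type Ccdc71 and Rbck1 each had 1 probe set at least 2-fold lower and 1 at least 2-fold higher, for Rbck1 at -1.05 and 1.75. The control probe sets behaved alike on both types. Across the 25 control probe sets above the floor on both, the log2 ratios correlated at 0.80, and the 3' to 5' signal ratio of Actb was 2.63 in knockout and 2.16 in wildtype on the first type and 2.76 and 2.31 on the second.

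On the first type 11 of 22 dermal matrix genes were lower in knockout, and 3 technical readings were weighed. Array scaling is argued against, since the highest list median under any scaling was -0.56. Less dermis in the knockout sample stays open: 25 endothelial, macrophage and adipocyte genes had a pooled median of -0.068 (95% bootstrap interval -0.31 to 0.23) and none was at least 2-fold lower (1, Scd1, was higher), but some are also expressed in epidermis, only 2 are endothelial (Eng -0.92, Pecam1 -0.74), and haemoglobin genes were lower too. Sex cannot be told apart from genotype, with Xist at a log2 ratio of at least 3.47 between the arrays. An effect of genotype was not tested apart from these, because 1 array per genotype measured the genes.

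Of 9 SPRR2 genes 4 were higher in knockout, and the median of the 9 was 0.96. More epidermis in the sample, raising all differentiation genes alike, is argued against. The SPRR2 median exceeded that of 31 other genes by 1.36 (95% bootstrap interval 0.72 to 1.80). These came from the keratin, cornified envelope and protease lists without loricrin, with Krt4, Krt7, Krt8, Krt13 and Krt19 among them. None of those 31 was at least 2-fold higher. The interval treats the 9 SPRR2 genes as separate, though their probe sets may share a transcript. Hemidesmosome and basement membrane genes were not in that comparison and had a median of 0.77, so a larger share of basal epidermis stays open. Array scaling is argued against by the lowest SPRR2 median of 0.95 under any scaling. A single transcript read by all 9 SPRR2 probe sets that name 1 gene stays open. Their ratios span 1.74, and 6.62% of 10000 random sets, drawn from the differences between 2 probe sets of a gene, spanned as much. The random sets were not matched on signal and include dimmer probe sets, so this share cannot decide the question. An effect of genotype, sex or litter stays open as untested, with 1 array per genotype.

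The log2 ratios of a gene agreed poorly between the array types, and noise between probe sets is a candidate explanation. Then 2 probe sets of a gene on the same arrays would correlate hardly better than across types. They correlated at 0.241 over 900 genes on the first type and 0.265 over 1156 on the second, on average 0.075 above the value between types (95% bootstrap interval -0.014 to 0.175). The interval is too wide to settle it, and RNA from other animals on the second type stays open.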
